A study of Mus musculus with 4 samples.

How the data were processed

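Gene expression was measured in mice with Affymetrix mouse genome arrays, a 3' expression platform on which each transcript is read by 1 or more sets of short probes. Per the labels, germ-free mice were colonized with a bacterium named only as L.NK2 (inoculum given as 1e+08, with no unit), and 2 weeks later intestinal epithelial cells (IEC) and Peyer's patch cells (PP) were taken from them and from germ-free (GF) mice. There were 4 groups of 1 array each, named GF-IEC, L.NK2-IEC, GF-PP and L.NK2-PP. How many mice stand behind each array is not given in the sources used here.

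Per the submitters' processing notes, the authors used MAS5, which gives each probe set a signal and a detection call of present, marginal or absent. Its version, scaling target and background settings are not given in the sources used here. The deposited signals are intensity values on a linear scale, neither log-transformed nor negative, for 45037 probe sets per array. Array medians lay between 22.9 and 23.3, so the 4 arrays had been put on a common scale before deposit. Affymetrix control probe sets are not analysed here, which leaves RNA integrity unchecked. The authors' deposited comparison tables also give, for each tissue, the ratio of the colonized signal to the germ-free signal. Recomputing that ratio from the signals gave the deposited value, within 0.0001 plus a millionth of the ratio, at 45037 of 45037 probe sets in each tissue. The colonized columns of these tables carry abbreviated names instead of L.NK2. They were assigned to the colonized arrays because each table is deposited as the L.NK2 against GF comparison of its tissue, and their signals equal those deposited under the L.NK2 sample at 45037 of 45037 probe sets.

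Gene symbols came from the deposited annotation and were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 38286 carried 1 symbol, 1367 carried several and 5384 carried none. Among those with 1 symbol, 35358 matched by Entrez identifier and 1813 received a newer symbol. Probe sets with several symbols or none were left out of gene comparisons. Each of the 20811 genes was represented by its probe set with the highest mean log2 signal over the 4 arrays. Coordinates are those of the deposited annotation, on mouse build GRCm38.

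For each tissue the log2 ratio of the colonized over the germ-free signal was computed and centred on its median over probe sets called present on both arrays. The shifts removed were 0.03 in IEC and -0.03 in PP. The GF-IEC over GF-PP ratio was centred in the same way, with a shift of -0.22. A gene counted as detected when called present on at least 1 of the 2 arrays compared. It was counted as higher or lower when the ratio reached 2-fold and the brighter array was called present. Where the dimmer array was called absent, the fold is given as "at least", against the higher of the dim signal and the lowest present signal on that array. The dim signal is itself noisy near background, so such a bound is not a strict limit and the true fold could be smaller. All folds, these bounds included, are after centring, so they differ by the removed shift from the ratio of the printed signals. With 1 array per group there is no spread between samples, so no p-value or standard deviation across samples was computed, and no difference below has a replicate check. The number of arrays limits the precision of every value. The spread of the log2 ratios between probe sets of the same gene gives only a technical scale. Its pooled standard deviation was 0.34 in IEC and 0.20 in PP on the log2 scale.

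Before the data were examined, 49 gene lists of cell types, gut regions and pathways were fixed, together with the size rule and 11 processing alternatives. For a list with at least 5 detected members, the median log2 ratio was placed among 10000 random lists of the same size, drawn from detected genes in 20 bins of mean log2 signal. The percentile describes these arrays and is not a test, because genes of a list vary together. Another 7 lists, such as stomach surface genes and Y-linked genes, were added after the main values had been seen. Those of escape genes, posterior Hox genes and immunoglobulin genes were set before their own results were seen. Genes were named by a rule also fixed in advance. In each tissue it took the 10 genes with the largest rise and the 10 with the largest fall, among genes with a present signal at or above the median present signal of the brighter array and with detected probe sets of 1 sign. From each list described it took up to 4 detected members with the largest absolute log2 ratio, and for the comparison of tissues up to 10 genes at least 2-fold different in both. Some of the genes this rule takes are not reported here.

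The procedure was tested on simulated arrays made from the germ-free signals with added noise of the size given above and 200 genes changed by known folds. For the simulated IEC comparison, run on 20811 genes, 64 of 67 genes changed 3-fold and 66 of 66 changed 8-fold were counted in the right direction, as were 4 of 67 changed 1.5-fold. Of 10447 unchanged detected genes, 30 were counted. For the simulated PP comparison, also on 20811 genes, the numbers were 67 of 67, 66 of 66 and 0 of 67, with 0 of 11840 unchanged genes counted. Of 200 random lists of 10 unchanged genes, 10 in IEC and 4 in PP fell outside the middle 95% of random lists. This simulation holds technical noise only and no difference between mice. Its noise was estimated from probe sets present on both arrays and was the same at every signal. Detection calls were copied from the germ-free array, and only genes present there were changed. The false counts therefore do not carry over to dim genes or to genes called absent on 1 array.

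The alternatives were signals without centring, quantile normalization, lowess of the ratio on signal (span 0.3), no detection filter, presence on both arrays, log2(signal + 32), the median over probe sets of a gene, only probe sets without the suffixes that mark shared sequence, thresholds of 1.5-fold and 3-fold, and the authors' deposited ratio and call. A further alternative, without X- and Y-linked genes, was added after the data had been seen. A shorter deposited sheet that repeats part of the Peyer's patch comparison was not used. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 drew the plots.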

Results

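The data are 4 expression arrays from mice, 1 per group: intestinal epithelial cells and Peyer's patch cells, each from germ-free mice and from mice colonized 2 weeks earlier with L.NK2. Peyer's patches are the organized lymphoid follicles of the small intestinal wall. The design asks how the bacterium alters transcription in the gut. Of 45037 probe sets, 25158 were called present on GF-PP, 24612 on L.NK2-PP, 20178 on GF-IEC and 18993 on L.NK2-IEC. Across probe sets present on both arrays of a pair, log2 signals correlated at r = 0.988 between the PP arrays and 0.974 between the IEC arrays, and at 0.735 to 0.746 across tissues. With 1 array per group, every fold below is the ratio of 1 array to another, without a replicate check.

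The 2 germ-free arrays were first set against each other to see whether they carried the transcripts of their labelled tissues. Epithelial markers were far higher on GF-IEC, with 19 of 19 detected members at least 2-fold higher and a median log2 ratio of 6.38. Examples chosen after their values were seen are Lgals4, a galectin of gut epithelium, 151-fold higher, and Epcam, an epithelial adhesion molecule, 60.2-fold higher. B cell markers were lower on GF-IEC for 18 of 18 detected members (median -5.28), and T cell markers for 19 of 21 (median -3.78). The brush border hydrolases and nutrient transporters were higher for 20 of 20 (median 5.44). Of 13271 detected genes, 5321 differed at least 2-fold, 2759 higher and 2562 lower on GF-IEC.

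In the epithelial pair, several genes of stomach surface cells and Xist were among the largest rises in the colonized array, and the colon and intraepithelial lymphocyte lists were lower, with 6 of 10 and 11 of 14 detected members past 2-fold. Gkn2, a gastrokine secreted by gastric surface mucous cells, was at least 450-fold higher (signal 12.5 on GF-IEC, 5752 on L.NK2-IEC), and its relative Gkn1 at least 183-fold higher. Tff2, a gastric trefoil peptide, was at least 63.6-fold higher and Muc5ac, the main secreted gastric mucin, at least 14.1-fold higher. On the other side, Saa1, an acute-phase serum amyloid, was at least 27.5-fold lower, Car1, a carbonic anhydrase of colonocytes, at least 11.6-fold lower, and Insl5, a peptide hormone of hindgut endocrine cells, at least 14.4-fold lower. By the size rule 173 of 11309 detected genes were higher and 184 lower. Of these, 45 and 71 respectively were called absent on the dimmer array.

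The remaining genes with the largest rises were Xist (69.5-fold), Gkn3 (50.9-fold), Anxa10 (at least 39.8-fold), Tff1 (23.6-fold), Ctse, the aspartic protease cathepsin E (17.2-fold), and Wfdc18 (log2 ratio 3.46, absent on GF-IEC). The largest falls also included Hao2, a peroxisomal hydroxy acid oxidase (26.4-fold), Sval1 (log2 ratio -4.32, absent on L.NK2-IEC), Tgm3 (at least 6.47-fold), Itih5 (6.42-fold), the water channel Aqp8 (5.74-fold), Rgs1 (5.71-fold) and Ggh (5.36-fold). Other detected probe sets of these genes gave smaller log2 ratios of 3.04 for Anxa10, 1.53 for Ctse, -0.70 for Tgm3 and -1.29 for Itih5. Larger ones were 7.13 for Xist, 8.16 for Gkn1 (7.52 at its brightest probe set) and -5.54 for Saa1 (-4.78). The Gkn2 probe set aligned to chromosome 6 from 87373370 to 87379398 on the plus strand of GRCm38. Those of Gkn1 (87346160 to 87347163) and Gkn3 (87383255 to 87383534) lay on the minus strand of the same chromosome. The Saa1 probe set aligned to chromosome 7 from 46751839 to 46754313, and that of Car1 to chromosome 3 from 14766215 to 14778442. In a list of stomach surface and antral genes written after these values were seen, and partly from them, 13 of 14 detected members were at least 2-fold higher and 0 lower (median 3.96). On GF-IEC 4 of the 14 were called present.

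**Figure D1:**
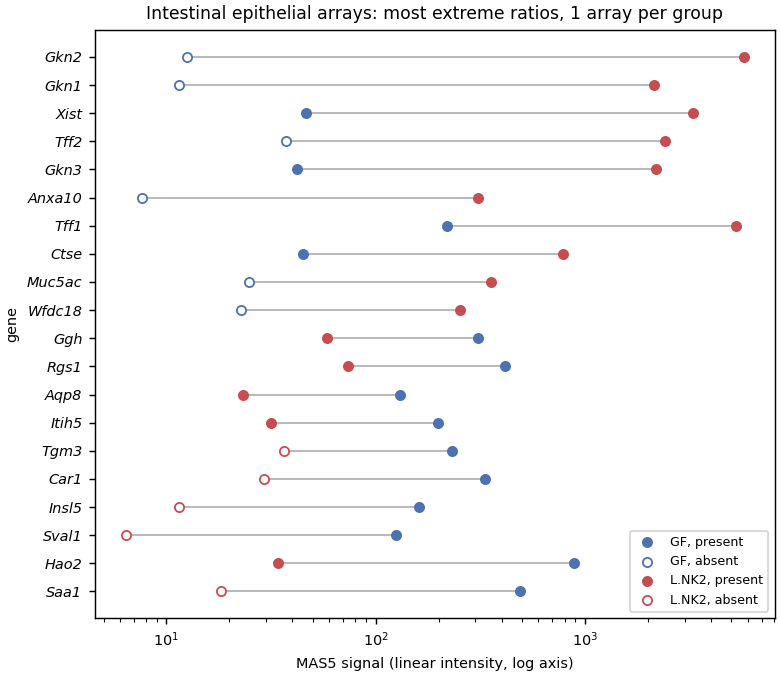
Signals of the 10 genes with the largest rise and the 10 with the largest fall in the epithelial pair. The x axis is the MAS5 signal (linear intensity on a log axis), each point is 1 array, blue is GF-IEC, red is L.NK2-IEC, and open points were called absent. Gkn2 runs from 12.5 to 5752, and Saa1 runs the other way, from 491 to 18.2.

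Gut-region lists differed within the same pair. Of 10 detected colon markers, 10 had negative log2 ratios and 6 were at least 2-fold lower (median -1.28, percentile 0 among 10000 random lists). Among them Hoxb13, a homeobox gene of the hindgut, was at least 8.02-fold lower. Distal small intestine markers had a median of -0.63 (percentile 0), with 2 of 11 at least 2-fold lower. These were Slc10a2, the ileal bile acid transporter (2.38-fold), and Nr0b2 (at least 2.15-fold), and Fabp6, the ileal bile acid binding protein, had a log2 ratio of -0.90. Proximal small intestine markers had a median of 0.16 (percentile 91.9), with 2 of 11 higher, Gip at 5.64-fold and Ada at 2.08-fold.

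Secretory and rare epithelial lineages went different ways in the colonized array. Tuft cell markers had the highest median of the fixed lists (2.48, percentile 100), with 5 of 7 detected members at least 2-fold higher, including Rgs13 (7.04-fold) and Alox5ap, the 5-lipoxygenase activating protein (5.59-fold). Enteroendocrine markers had a median of 0.71 (percentile 100), with 4 of 16 higher. They included the hormone gene Gip and Ghrl, which encodes ghrelin (3.27-fold). Goblet markers had a median of 0.41 (percentile 99.99) and 0 of 15 past 2-fold. Paneth cell markers had a median of -0.57 (percentile 0.025), with 1 of 6 at least 2-fold lower, the phospholipase Pla2g2a (2.04-fold). Cell cycle genes had positive log2 ratios in 28 of 28, with a median of 0.38 (percentile 100). Of these only Tyms, from a dim probe set, passed 2-fold. General epithelial markers had a median of -0.16 with 0 of 19 past 2-fold, inside the middle 95% of random lists. The same array carried the stomach surface transcripts given above (median 3.96).

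Lymphocyte transcripts were lower in the colonized epithelial array. Of 14 detected markers of intraepithelial and cytotoxic lymphocytes, 11 were at least 2-fold lower (median -1.46, percentile 0). Klrd1, a natural killer receptor chain, was 5.13-fold lower, and the granzymes Gzma and Gzmb were 3.59-fold and 3.58-fold lower. T cell markers had a median of -0.76 (percentile 0), with 5 of 14 at least 2-fold lower, among them Cd3g (4.29-fold) and Cd8a (3.18-fold, with a log2 ratio of -0.58 at another probe set). Neutrophil markers went the other way (median 1.06, percentile 100), with 4 of 6 higher, including S100a9 (2.09-fold) and S100a8 (2.08-fold). Regulatory and follicular helper T cell genes had a median of -0.48 with 1 of 5 lower, and macrophage and dendritic cell markers -0.35 with 2 of 13 lower. Colon markers were lower on the same array, as given above, and so were the haemoglobin alpha probe sets shared by Hba-a1 and Hba-a2, 11.9-fold to 17.9-fold, looked up after the values were seen.

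Genes known to be induced in gut epithelium by microbes did not move together. Of 14 detected members 1 was at least 2-fold higher, 2 were lower and the median was 0.13 (percentile 93.1). Saa1 and Saa2 were at least 27.5-fold and 5.02-fold lower, but their probe sets align to the same interval of chromosome 7, carry shared-sequence suffixes and do not tell these genes apart. Ido1, the tryptophan-degrading dioxygenase, was 2.71-fold higher. The antimicrobial lectins Reg3g and Reg3b, looked up after the values were seen, had log2 ratios of 0.56 and 0.20. MHC class II genes had a median of 0.59 (percentile 100) with 1 of 8 lower, but the sign turned to -0.43 when only probe sets without shared-sequence suffixes were used. Smooth muscle markers had a median of 0.80, with Actg2 at least 3.33-fold higher among 9 detected. Heat shock genes (median 0.32), unfolded protein response genes (0.35) and ribosomal proteins (0.12) also lay above the middle 95% of random lists. Type I interferon genes (-0.24), fatty acid oxidation genes (-0.26), xenobiotic genes (-0.38) and pancreatic acinar markers (-0.42) lay below it. Among the xenobiotic genes, Cyp2c55 was 4.72-fold lower and Abcb1a 2.25-fold lower.

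Of 43 lists with at least 5 detected members in the epithelial pair, 22 lay inside the middle 95% of random lists. Besides those already given, these were stem cell markers (median 0.02), interferon gamma and MHC class I genes (0.11), fat absorption (-0.07), cholesterol synthesis (-0.14), digestion and absorption (-0.16), B cells (-0.36), germinal centre B cells (-0.14), plasma cells (0.05) and immunoglobulins (0.06). The others were M cells and follicle-associated epithelium (0.17), lymphoid stroma (-0.13), fibroblasts (0.27), immediate early genes (-0.10), the circadian clock (-0.20), tight junctions (-0.13), inflammatory cytokines (0.03), pattern recognition (-0.04), epithelial cytokines (-0.19) and the respiratory chain (-0.08). The T helper 17, mast cell, endothelial, red blood cell and adipocyte lists had 1 to 4 detected members. Their medians were -0.26, -0.50, 0.02, -0.86 and -0.002. The red blood cell value was that of Car2 alone. The haemoglobin alpha probe sets given above carry several symbols and did not enter it. The enteric neural list had 0 detected members.

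In the Peyer's patch pair, plasma cell and protein-folding transcripts were higher in the colonized array, while type I interferon and stromal transcripts were lower. Prdm1, the transcription factor that drives plasma cell differentiation, was 6.56-fold higher and Derl3, a component of endoplasmic reticulum degradation, 7.18-fold higher. Ifit3 and Ifit1, antiviral genes induced by type I interferon, were 5.79-fold and 4.94-fold lower. Gzmk, a granzyme of cytotoxic T cells, was 7.49-fold higher, and Slpi, a secreted protease inhibitor, 5.36-fold higher from a signal of 1763 on GF-PP. In the same pair Xist was 185-fold higher and Y-linked genes were lower. By the size rule 119 of 12519 detected genes were higher and 95 lower.

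Of 13 detected plasma cell genes, 13 had positive log2 ratios and 9 were at least 2-fold higher (median 1.78, percentile 100). Unfolded protein response genes had a median of 1.46 (percentile 100), with 14 of 17 at least 2-fold higher and 0 lower. Among them Chac1, a glutathione-degrading enzyme, was 5.43-fold higher, the chaperone cofactor Dnajb9 3.66-fold higher, and asparagine synthetase, Asns, 3.40-fold higher. Creld2 (5.30-fold) and Edem1 (log2 ratio 1.53) belong to both lists. The immunoglobulin genes with their own probe sets had a median of -0.39 (percentile 0), with 2 of 8 lower, Ighg3 at 4.86-fold (log2 ratio -0.15 at its other detected probe set) and Igk at 2.22-fold. B cell markers had a slightly negative median (-0.18, percentile 0.020), with 12 negative and 6 positive log2 ratios and 0 of 18 past 2-fold. Germinal centre markers had a median of -0.12 with 0 of 12.

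Of 23 detected genes of the type I interferon list, 23 had negative log2 ratios in this pair and 13 were at least 2-fold lower (median -1.10, percentile 0). Rsad2 (3.26-fold lower, with a log2 ratio of -0.36 at another probe set) and Rtp4 (2.82-fold lower) followed Ifit3 and Ifit1. By contrast, genes induced by interferon gamma and of MHC class I had a median of 0.09 (percentile 98.6) with 0 of 23 past 2-fold. The Ifit3 probe set aligned to chromosome 19 from 34583530 to 34589036 and that of Ifit1 from 34640870 to 34650009, on the plus strand of GRCm38. That of Prdm1 aligned to chromosome 10 from 44437174 to 44458748, on the minus strand.

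Medians of stromal, vascular and myeloid lists were negative in the colonized patches. Fibroblast and matrix genes had a median of -0.79 (percentile 0), with 5 of 16 at least 2-fold lower, such as Mgp (3.93-fold) and fibronectin, Fn1 (at least 2.96-fold). Lymphoid stromal markers had the same median to 2 decimals, with 5 of 10 lower, including the addressin Madcam1 (2.52-fold) and the B cell chemokine Cxcl13 (2.24-fold). Within that list Glycam1, an adhesion ligand of high endothelial venules, was instead 2.53-fold higher. Smooth muscle markers had a median of -0.56, endothelial markers -0.44 and macrophage and dendritic markers -0.30, each at percentile 0, with 0 of 9, 1 of 10 and 0 of 23 members at least 2-fold lower. The complement gene C1qb was 1.99-fold lower.

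Medians of T cell lists were modestly positive in the colonized patches, with few members past 2-fold. T cell markers had a median of 0.27 (percentile 100) with 0 of 21 past 2-fold, led by the costimulatory receptor Cd28 (1.91-fold). Of 16 regulatory and follicular helper genes, 3 were at least 2-fold higher (median 0.39, percentile 100): Il10 (3.54-fold, from a signal of 7.81), Ctla4 (2.42-fold) and Pdcd1 (2.12-fold). Cytotoxic markers had a median of 0.20 (percentile 99.99), with 2 of 19 higher, Gzmk and Fasl (3.11-fold). Cell cycle genes had negative log2 ratios in 27 of 27, with a median of -0.31 and 0 past 2-fold.

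Heat shock genes split in the colonized patches. Hspa1b and Hspa1a, which encode inducible Hsp70, were 5.24-fold and at least 4.17-fold lower, while the co-chaperone Hsph1 was 3.34-fold higher and Hspa4l 2.01-fold higher, and the list's median was 0.29 (percentile 100). The immediate early list had 2 of 19 at least 2-fold lower, Ccn1 (log2 ratio -1.85, absent on L.NK2-PP) and Jun (2.29-fold), with a median of -0.22. Among the other largest changes, Slc15a2, a peptide transporter, was 25.3-fold higher by its brightest probe set but had a log2 ratio of 0.49 at its other detected one. Oosp1 was 9.94-fold higher and Prg2, eosinophil major basic protein, 5.49-fold higher. Postn, the matrix protein periostin, was 4.67-fold lower, Csn2, a casein, 4.63-fold lower, and the linker histone gene H1f4 3.68-fold lower.

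**Figure D2:**
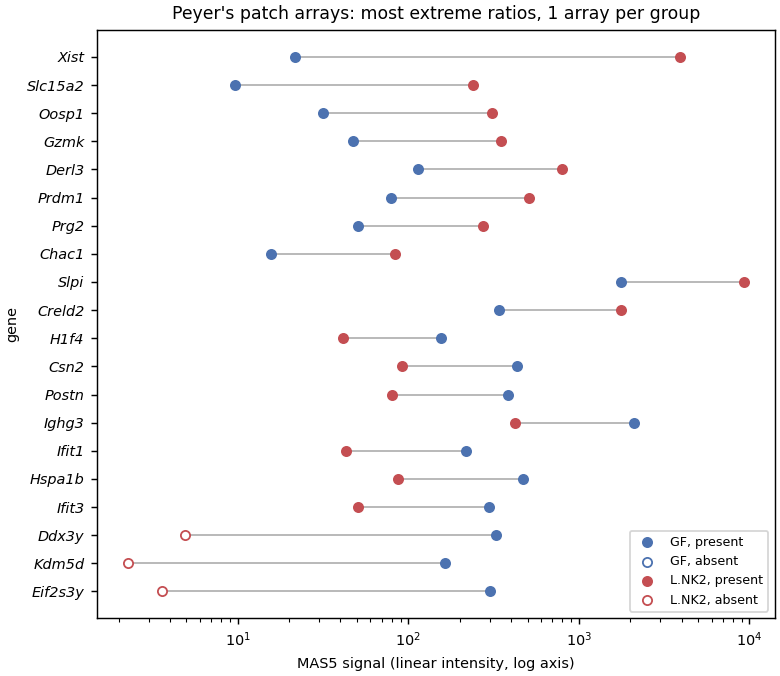
Signals of the 10 genes with the largest rise and the 10 with the largest fall in the Peyer's patch pair. The x axis is the MAS5 signal (linear intensity on a log axis), each point is 1 array, blue is GF-PP, red is L.NK2-PP, and open points were called absent. Slpi runs from 1763 to 9258, Ifit3 runs the other way from 299 to 50.6, and the lowest points are Y-linked genes.

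Of 38 lists with at least 5 detected members in the Peyer's patch pair, 13 lay inside the middle 95% of random lists. Besides the germinal centre markers already given, their medians were 0.17 for stem cell markers, -0.06 for fat absorption, -0.09 for fatty acid oxidation, 0.11 for digestion and absorption, -0.09 for epithelial markers, 0.05 for T helper 17 genes and 0.11 for the circadian clock. Tight junctions had -0.19, inflammatory cytokines -0.04, pattern recognition -0.08, the respiratory chain -0.03 and ribosomal proteins 0.003. Other lists beyond that range were neutrophils (0.26), MHC class II (-0.19), cholesterol synthesis (-0.24), mast cells (-0.25), M cells (-0.25), epithelial cytokines (-0.34), microbe-induced epithelial genes (-0.32) and xenobiotic genes (-0.21), and the sign of the last 2 depended on the detection filter. Paneth, goblet, enteroendocrine, tuft, proximal, distal, pancreatic, red blood cell and adipocyte lists had 1 to 4 detected members, with medians of -0.23, -0.03, -0.12, -0.09, -0.20, 0.37, 0.09, -0.21 and -0.58. The red blood cell value was again that of Car2 alone. The colon and enteric neural lists had 0 detected members.

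**Figure D3:**
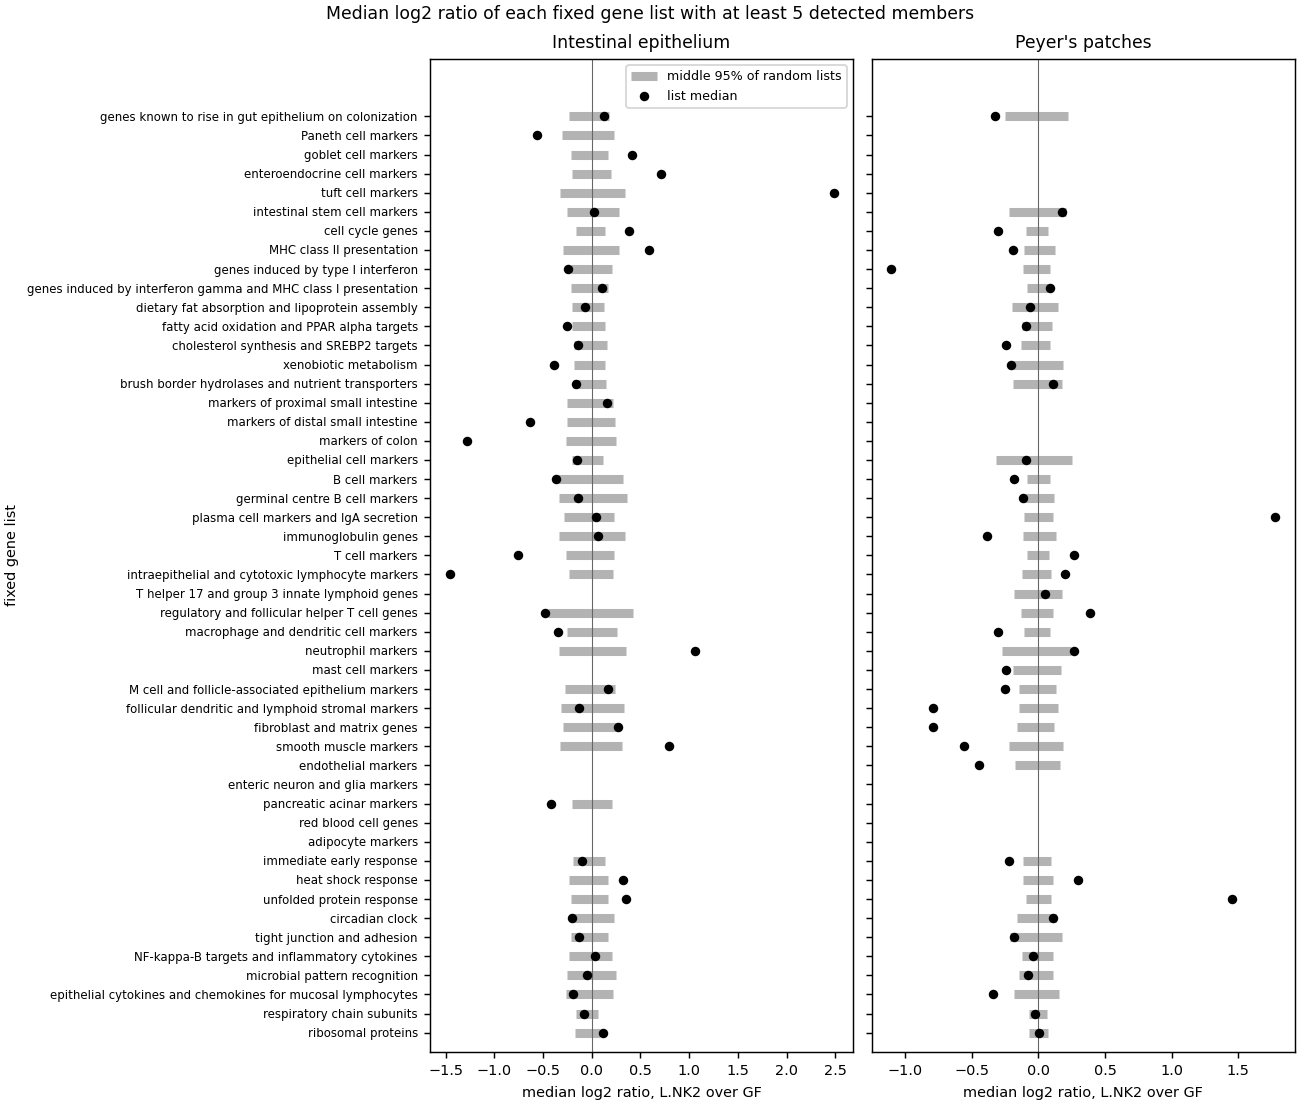
Median log2 ratio of colonized over germ-free signal for each fixed list with at least 5 detected members, in epithelium and in Peyer's patches, from 1 array per group. Points are list medians and grey bars the middle 95% of 10000 random lists matched on signal. Tuft markers lie at 2.48 and colon markers at -1.28 in epithelium, and plasma cell genes lie at 1.78 and type I interferon genes at -1.10 in the patches.

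Sex-linked transcripts differed between the colonized and germ-free arrays of both tissues, alongside all of the groups above. Xist, the noncoding RNA of the inactive X chromosome, was 185-fold higher on L.NK2-PP and 69.5-fold higher on L.NK2-IEC. In the patches the Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty were called absent on L.NK2-PP, at least 82.3-fold, 71.3-fold, 65.4-fold and 14.2-fold lower than on GF-PP. On L.NK2-IEC the same 4 genes were still called present, at 3.56-fold, 2.19-fold, 2.01-fold and 2.78-fold lower than on GF-IEC. Other detected probe sets of these genes kept the sign but not the size, with log2 ratios in the patches of -0.23 for Eif2s3y, -0.72 for Kdm5d, and -7.92 and -5.11 for Ddx3y. The counts without X- and Y-linked genes were 167 higher and 176 lower in IEC, and 112 higher and 87 lower in PP.

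**Figure D4:**
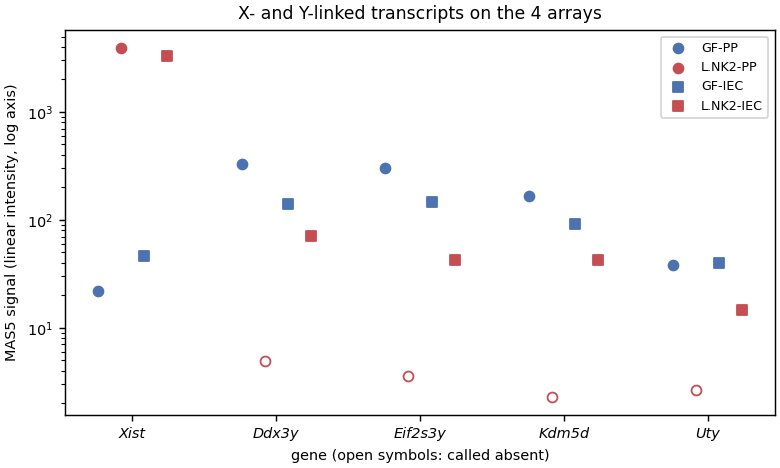
Signals of Xist and of 4 Y-linked genes on the 4 arrays. The y axis is the MAS5 signal (linear intensity on a log axis), blue marks germ-free and red colonized arrays, circles mark PP and squares IEC, and open symbols were called absent. Xist reaches 3936 on L.NK2-PP and 3303 on L.NK2-IEC, and Ddx3y is 4.88 on L.NK2-PP and 70.5 on L.NK2-IEC.

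The differences in the 2 tissues were then compared, to see whether colonized and germ-free arrays differed alike in both. Xist and Hsph1 (3.07-fold in IEC, 3.34-fold in PP) were higher in both colonized arrays, and Cxcl13 (2.41-fold and 2.24-fold) and the water channel Aqp4 (2.26-fold and 2.69-fold) were lower in both. Another Aqp4 probe set had a log2 ratio of 0.27 in IEC. Gpr171 was 3.02-fold lower in IEC and 2.90-fold higher in PP, and Fasl at least 2.68-fold lower and 3.11-fold higher. Zc3h6 was lower in both (2.29-fold and 2.86-fold). Anxa10 was higher in both, but its PP value came from a dim probe set with a shared-sequence suffix and turned to a log2 ratio of -0.02 without such probe sets. Across 10006 genes detected in both tissues the log2 ratios correlated at Pearson r = 0.01 and Spearman rho = -0.07. Without Xist and the 4 Y-linked genes, Pearson r turned to -0.045. Genes are not independent replicates, so no p-value is given. At least 2-fold higher in both were 7 genes, against 1.09 if the lists were independent, and lower in both were 7, against 0.870. In opposite directions there were 6 genes higher in IEC and lower in PP, against 0.924, and 3 lower in IEC and higher in PP, against 1.03. Of the 14 genes shared in direction, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty are sex-linked.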

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

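Differences between the 2 tissues given here were not tested, since each tissue has 1 array per group; they are picked out because the ratio had opposite signs in epithelium and Peyer's patches. Among gene lists, those whose medians lay beyond the middle 95% of random lists on opposite sides are given as the epithelial median minus the patch median, on the log2 scale. That difference was 0.69 for cell cycle genes, 0.77 for MHC class II genes, -1.02 for T cell markers, -1.66 for intraepithelial and cytotoxic lymphocyte markers, -0.87 for regulatory and follicular helper T cell genes and 1.36 for smooth muscle markers. The epithelial MHC class II median changes sign with the choice of probe sets.

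The same difference was computed for the 9 genes at least 2-fold higher in 1 tissue and at least 2-fold lower in the other. Clusterin, Clu, differed most, by 4.15, with 8.30-fold higher signal in colonized epithelium and 2.13-fold lower signal in colonized patches. Differences of the same sign were 3.38 for Ighg3, 2.55 for C1s1, 2.44 for complement C3, 2.38 for Fabp4 and 2.38 for Cpe. The epithelial value of Ighg3 came from a dim probe set. Lower in epithelium and higher in patches were Gpr171 (-3.13), Fasl (-3.06) and Tent5c (-3.03).

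Probe sets that the annotation assigns to several genes were outside the gene comparisons, and some differed at least 2-fold with a present call on the brighter array: 25 in epithelium and 31 in patches. The families named here were chosen after their values were seen. Haemoglobin alpha probe sets (Hba-a1 and Hba-a2) were 11.9-fold to 17.9-fold lower on L.NK2-IEC, and the beta probe set was 13.3-fold lower. A probe set shared by major urinary protein genes, Mup1 among them, had a signal of 6.17 with an absent call on GF-IEC and 326 with a present call on L.NK2-IEC, while another 2 probe sets that list Mup1 were absent on both arrays, at 48.0 and 54.0 and at 4.84 and 5.19. Detected probe sets of the T cell receptor gamma genes (Tcrg) were 2.55-fold to 4.74-fold lower on L.NK2-IEC. In the patches, 3 probe sets shared by Igha and Igh-VJ558 were 2.85-fold, 3.80-fold and 4.07-fold lower on L.NK2-PP. A probe set shared by Igh, Ighg1 and Ighm was instead 2.40-fold higher and another shared by Ighg2c and Ighm 3.36-fold higher. Kappa probe sets also went both ways. A probe set shared by Igk-V1 and Igkv9-120 was 6.63-fold lower, and 1 shared by Igk-V28 and Igkv6-14 was 2.82-fold higher.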

How the results depend on the processing

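Of the alternatives below, only leaving out X- and Y-linked genes was chosen after the data had been seen. Counts of genes past the size rule stayed within 1.5 times the values reported under uncentred signals, quantile normalization, lowess, no detection filter, the authors' ratio, probe sets without shared-sequence suffixes, and no sex-linked genes. Requiring presence on both arrays left 108 lower genes in IEC and 3375 different genes between the germ-free tissues, since fewer genes qualify. With log2(signal + 32), which shrinks ratios of dim genes, 60 were higher and 56 lower in IEC, and 56 higher and 39 lower in PP. The median over probe sets gave 110 higher in IEC and 60 lower in PP. At 1.5-fold the counts were 752 and 653 in IEC and 357 and 346 in PP; at 3-fold they were 38 and 55, 44 and 19, and 3352 between the germ-free tissues. The share of higher genes in PP was 55.6% at 2-fold and 69.8% at 3-fold. In IEC it went the other way, from 48.5% to 40.9%. The IEC share was 52.3% without centring and 53.8% with presence on both arrays. The correlation of the tissues' ratios ranged from -0.04 to 0.02 over 10 alternatives.

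A change of sign was counted only where the reported value was at least the spread between probe sets of a gene (0.34 in IEC, 0.20 in PP). Smaller values that crossed 0 are not among the counts that follow. Of 810 list medians under alternatives, 4 changed sign by this rule. In PP these were the microbe-induced list (0.045) and the xenobiotic list (0.025) without a detection filter, and the xenobiotic list (0.082) with presence on both arrays. In IEC the MHC class II list gave -0.43 with only plain probe sets. Of 4139 values of named genes, 13 changed sign by the same rule. With the median over probe sets these were Ighg3 (-0.075) and Acta2 (-0.027) in IEC, and Lgr5 (-0.0021), Cdca7 (0.032), Fkbp11 (-0.0059) and Tpsb2 (-0.27) in PP. With only plain probe sets they were Acta2 (-0.027) and Hyou1 (-0.011) in IEC, and Fkbp11 (-0.14), Tpsb2 (-0.88), Tpm2 (0.34), Cycs (0.034) and Anxa10 (-0.024) in PP. The cause was not tested. A further 33 list medians and 248 named-gene values moved by more than the spread between probe sets of a gene, 27 and 229 of them toward 0. Of the 248, 152 moved with log2(signal + 32). Ratios of probe sets called absent on an array are limited by background, and MAS5 values near it are noisy.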

Other observations

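Among the tests below, those of escape genes, posterior Hox genes, immunoglobulin genes and the 5 cell type lists were set before their results were seen; the others were chosen after. Each pattern comes from 1 array per group, so every explanation of the stomach, colon and plasma cell patterns is a hypothesis.

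Xist was higher and Y-linked genes were lower in both colonized arrays. In the patches the signals argue against germ-free and colonized mice of the same sex. The 4 Y-linked genes were called present on GF-PP (Ddx3y at 326) and absent on L.NK2-PP (Ddx3y at 4.88), while Xist went from 21.7 to 3936. The genes Kdm5c, Kdm6a, Eif2s3x and Ddx3x, which escape X inactivation, had a median log2 ratio of 0.57 in the patches. The colonized epithelial array is consistent with RNA from mice of both sexes, since 4 of 4 Y-linked genes were called present beside high Xist. Sex is therefore confounded with colonization here, and no effect of the bacterium can be separated from it.

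Stomach surface genes were higher and colon genes lower in the colonized epithelial array. An admixture of acid-secreting mucosa is left undecided. Atp4a, Atp4b, Cblif and Pgc had a median log2 ratio of 0.28 whatever their call. Pgc alone went from absent to present (0.65). The others were called present on neither array, so the median rests mostly on values near background. A different share of gut regions stays a candidate explanation, which the lists do not decide. The proximal list's median exceeded the distal list's by 0.79, but the bound was set with that value known, so the comparison could not fail. The proximal median (0.16) lay inside the range of its random lists (-0.25 to 0.22). The difference therefore rests mostly on the lower distal median (-0.63) given above and adds no separate support. The set of posterior Hox genes fixed for this test left out Hoxb9 and Hoxb13. That set decides nothing, since only Hoxa10 was detected (-0.27). Hoxb13 had a log2 ratio of -3.00, but it is in the colon list that defines the pattern and adds no separate support. Surface or antral mucosa carried along at dissection, and a response of the epithelium to the bacterium, both stay open.

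Plasma cell genes were higher in the colonized Peyer's patch array. Prdm1, Irf4, Sdc1, Tnfrsf17 and Slamf7, picked after the values were seen as members without a role in protein folding, had a median log2 ratio of 1.803. They ranged from 0.29 for Slamf7 to 2.71 for Prdm1. Being part of the list that defines the pattern, they give no separate support. A fall in all 5 cell type lists alike is argued against by the T cell list, the highest of them at 0.27. The B cell (-0.18), macrophage (-0.30) and epithelial (-0.09) medians were negative, as was the fibroblast median given above. A lower share of those cells without T cells was not tested and stays open. A larger share of plasma cells cannot be told apart from activation of those present. Of 6 genes set for this test, Jchain (0.70) and Ighm (-0.61) were the 2 detected by probe sets of their own, with a median of 0.044. Jchain is also in the plasma cell list that defines the pattern, so its value gives no separate support. Probe sets that Igkc, also among the 6, shares with other kappa genes had log2 ratios of 0.29, 0.33 and 0.39. Other immunoglobulin transcripts went both ways, with a list median of -0.39. Igha probe sets were 2.85-fold to 4.07-fold lower, and a probe set shared by Ighg2c and Ighm was 3.36-fold higher. A difference in sex, given above for the same arrays, also stays untested as a cause of this pattern and of the lower interferon genes.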
